A study of Mus musculus with 6 samples.

How the data were processed

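Total RNA from 6 preparations of sorted mouse cells, 3 GFP-low from skin and 3 GFP-high from wounds, was labelled with Cy3 and hybridised to 1-colour Agilent miRNA arrays, per the labels. Per the file headers the arrays, all on 1 slide, were read with Agilent Feature Extraction 10.7.3.1. The deposited scanner files hold spot intensity on a linear scale: a background-subtracted processed signal, which can be negative, the median signal and local background of each spot, and a total signal per miRNA, none of them normalized between arrays. The authors also deposited a table of log2 values, whose processing is not given in the sources used here. Each of its 6 columns equals the log2 total signal per miRNA of 1 array minus a constant, within 0.001, over the 656 of its 691 rows whose names occur in the scanner files. The column medians lie between -12.53 and -11.76, because most values of a column sit at its lowest value. That table's column numbers and the numbers in the array titles do not match for any of the 6, so the scanner files, whose samples are recorded with them, gave the main values.

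For each of the 1928 probes (5 to 20 spots a probe, 1 to 4 probes a miRNA name) the processed signal was averaged over the spots without outlier flags. It was divided by the array's 75th percentile over the probes well above background on all 6 arrays. Probes of a miRNA were averaged on the linear scale, raised to a common floor of 0.0253 (-5.30 on the log2 scale, the median over arrays of the lowest scaled signal that was well above background) and taken to log2. The floor compresses differences of dim miRNAs. A probe counted as well above background when over 50% of its spots carried the scanner's flag. A miRNA was tested when at least 1 of its probes was so on all 3 arrays of at least 1 group; 222 of 690 names passed, 156 were well above background on all arrays and 416 on none. Of the tested miRNAs 7 lay at the floor on every array, since the mean over their probes was below it. Controls were left out, and 0 spots were saturated. The scaling percentile was 786 to 1772 intensity units against a median local background of 49.0 to 55.5, and between 2.14% and 3.11% of spots were flagged as outliers.

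The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided, R 4.3.3) with Benjamini-Hochberg adjustment over tested miRNAs at 0.05. Where no array of a group was well above background, the fold is given as at least N-fold: the mean of the other group against the mean of, per array, the higher of the lowest signal well above background and the dim signal itself. On the skin arrays that lowest signal was -5.37, -5.29 and -5.77 on the log2 scale, so bounds against skin can exceed the fold from the common floor. 19 lists of miRNAs were written from general knowledge, and the 14 with at least 3 tested members were compared with the other tested miRNAs by camera, with a preset correlation of 0.01 and with an estimated one. fry tested them against no change; each test was adjusted over the 14. A miRNA belongs to a list by its name without arm, so both arms count. Named miRNAs are the 12 largest increases and 12 largest decreases among adjusted p under 0.05 with groups that do not overlap, both arms of miR-127, the 3 smallest p of each list with at least 3 tested members and all tested members of smaller lists, 59 in all. The design, lists, naming rule and most alternatives were chosen before the data were examined.

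Alternatives covered the scaling (75th percentile of all probes, median, quantile, none), normexp background correction with an offset of 50, the total signal per miRNA, the summary over probes, the floor, the filter on dim miRNAs, limma with trend or array weights, the row on the slide as a block, each array left out and the authors' log2 table. After the data were seen, the authors' table with columns matched by their values, a run without names that carry an old registry version, and domain membership by gene order were added. Normexp used the median signal, because the files held no mean signal. Gene order and the distances between neighbouring genes came from a table of the GRCm38.p6 assembly, of which no coordinates are printed. It placed 55 of the 57 list members between Dlk1 and Dio3, where it holds 61 miRNA genes.

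On simulated arrays built from the skin arrays, with 183 miRNAs tested, limma called 51% of changes of 1.49-fold, 89% of 2-fold and 97% of 4-fold with the right sign, and 1.14% of unchanged miRNAs. In 20 simulations without change 1 had a list called by camera, and a let-7 family lowered 2-fold was called in 20 of 20. These simulations hold no correlation between miRNAs. Changed miRNAs were drawn from those well above background on all 3 skin arrays, and very small spreads were replaced by the median spread. Rises of miRNAs undetected in skin were thus not simulated, and the rates do not carry over to calls with a group at the floor. Figures were drawn with matplotlib 3.10.9.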

Results

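MicroRNA levels were measured on 1-colour microarrays in sorted mouse cells that carried neither CD45, a surface marker of blood cells, nor CD31, a surface marker of endothelium. The mice expressed GFP under control of the smooth muscle actin (SMA) gene, whose product marks contractile cells such as myofibroblasts. Cells with weak GFP, described by the submitters as fibroblast-like, came from skin, and cells with strong GFP, described as myofibroblasts, came from wounds 7 days after injury. Each group had 3 preparations on 1 array each, named here by the sample numbers in the labels: 1, 2 and 5 for skin and 3, 4 and 6 for wound. No label states whether the preparations came from separate animals, so the p-values measure the spread between these preparations, which may be partly technical. Tissue and GFP level changed together, and each difference covers both.

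The arrays held probes for 690 miRNA names, of which 201 ± 19.9 (mean ± SD, n = 3) were well above background on the skin arrays and 221 ± 11.2 on the wound arrays. That difference did not exceed the spread between preparations (exact two-sided permutation test, p = 0.3, where 0.1 is the smallest p that 3 against 3 arrays allow). Over the 222 tested miRNAs, log2 values correlated across miRNAs at r = 0.985 to 0.992 between arrays of 1 group and at 0.846 to 0.883 between arrays of different groups. The number of arrays limits the precision of every value below.

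The comparison asked which miRNAs differed between wound myofibroblasts and the GFP-low cells of skin, and whether miR-127-3p and the other miRNAs of the imprinted Dlk1-Dio3 domain, which the series title names, were among them. Most of the domain's detected miRNAs were higher in the wound cells, as were miR-21a-5p and the X-linked miR-322 and miR-503. The miR-29 and miR-26 families, miR-101a-3p, miR-10b-5p, miR-218-5p and miR-181a-5p were lower. In all, 144 of 222 tested miRNAs differed at a Benjamini-Hochberg adjusted p under 0.05 in limma, 98 of them higher and 46 lower in the wound cells (68.1% higher). Their 3 wound values all lay on 1 side of their 3 skin values in each of the 144. Of all tested miRNAs 69.8% were separated in this way. Chance gives 10% for a miRNA picked without regard to the groups. The filter on dim miRNAs used the groups, so 10% is no reference for this set. Differences over 2-fold were found for 60 of the higher and 22 of the lower miRNAs.

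The split between higher and lower depended on how the arrays were scaled. The median difference over all tested miRNAs was 0.38 on the log2 scale under the main scaling, and it moved by -0.57 with the 75th percentile of all probes, by -0.38 with the median or quantile normalization and by -0.46 with no scaling. The share of higher calls was then 40.6%, 50.4%, 50.4% and 50.0%, in that order. Under each of the main scaling and these alternatives, 5 scalings in all, 50 miRNAs were called higher and 39 lower, and 21 of the 144 calls turned sign in at least 1 of them. Under quantile normalization 3 of the miRNAs passed in the direction opposite to their main call. In 42 of the 144, all arrays of a group lay at the floor set for dim signals, where no spread is measured, so that their standard errors and p-values are too small. The changed miRNAs numbered 78 with a floor 4 times as high and 23 with normexp background correction. The groups follow the array titles; the deposited table numbers its columns in another order, and by those numbers 1 miRNA changed.

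**Figure D1:**
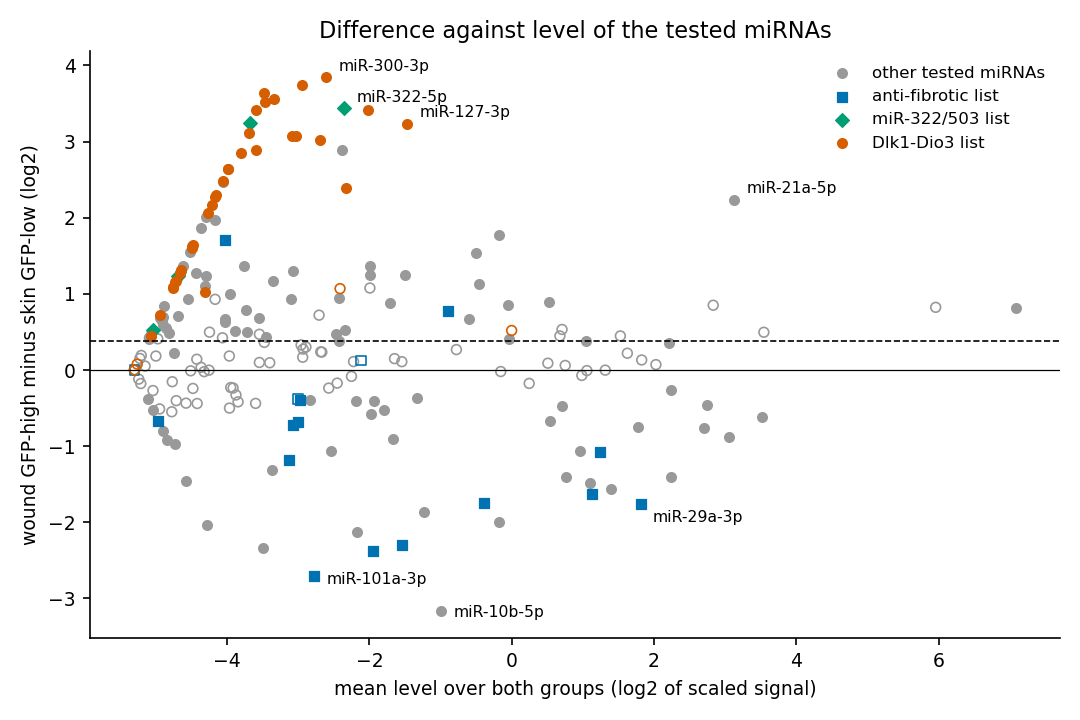
Log2 difference, wound GFP-high minus skin GFP-low, against the mean log2 level for the 222 tested miRNAs; filled symbols passed an adjusted p of 0.05, colours mark 3 lists fixed beforehand, and the dashed line is the median difference of 0.38. The points on the rising left edge lay at the floor in skin; most Dlk1-Dio3 miRNAs sit high above the line, and miR-10b-5p fell by 3.17.

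miR-127-3p was raised on all 3 wound arrays. Its log2 level was -3.09 ± 0.13 (mean ± SD, n = 3) on the skin arrays and 0.15 ± 0.06 on the wound arrays, a 9.42-fold difference (log2 3.24, SE 0.08, adjusted p = 3.8e-06 in limma) and 2.86 above the median of all tested miRNAs. The other arm of the same precursor, miR-127-5p, was not well above background on any array and was not tested.

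The Dlk1-Dio3 domain is an imprinted region that holds one of the largest miRNA clusters of mammals, expressed from the maternal chromosome. Of 74 names of the list on the array 38 were tested, and 34 of these were higher, 0 were lower and 4 did not pass (34 also passed when adjusted over the list alone). The 19 members not well above background in skin passed the filter only through the wound arrays. They could hardly come out lower, so for them the count of 0 lower shows nothing. The series title names this domain, so the list is not independent evidence of its direction. Its median log2 difference was 2.29, which is 1.91 above the median of all tested miRNAs, and 2.42 with the 19 members that were not well above background in skin set to their bounds. The list stood above the other tested miRNAs in camera with a preset correlation (adjusted p = 2.1e-10), but not with an estimated correlation (adjusted p = 0.203). fry, which asks whether members move 1 way, gave an adjusted p of 1.4e-06. It tests against no change and passed for every tested list except the keratinocyte, blood cell and Sfmbt2 lists, so it does not set the domain apart. Under the 5 scalings 31 to 34 members were called higher and 0 lower. Higher members numbered 13 with normexp, 21 with a floor 4 times as high and 12 among miRNAs well above background on all arrays, where fewer are tested. The size of the rise depended on the processing. With normexp, run on median signals with an offset, the list's median lay 0.25 above that of all tested miRNAs. With a floor 4 times as high, the list's median lay 0.50 above that of all tested miRNAs. It lay 3.07 above with total signals per miRNA and 2.84 above among miRNAs well above background on all arrays.

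Among members measured on both sides, miR-300-3p was 14.3-fold higher (log2 3.84, SE 0.19), miR-377-3p 11.7-fold, miR-382-5p 11.4-fold and miR-379-5p 10.68-fold. miR-376b-3p was 13.4-fold higher but well above background on only 2 of the 3 skin arrays (SE 0.44). miR-337-5p, miR-434-3p and miR-329-3p rose 8.69-fold, 8.44-fold and 8.43-fold. In skin miR-410-3p, miR-154-3p, miR-380-3p and miR-382-3p were not well above background on any array, and their wound levels were at least 14.02-fold, 12.0-fold, 5.09-fold and 2.72-fold higher. The members that did not pass were miR-494-3p (0.52), miR-376c-3p (1.07), miR-134-5p (0.08) and miR-376a-5p (at the floor on all arrays), named here after their values were seen. Counting members by gene order in the reference in place of the list gave 36 higher of 40 tested. Counted by the list, the higher members spanned the domain, with 9 of 9 tested between Dlk1 and the noncoding gene Rian, 2 of 2 within Rian and 23 of 27 between Rian and Dio3. These counts hold for the main scaling. miR-433-3p between Dlk1 and Rian and miR-370-3p within Rian were each called under only 1 of the 5 scalings.

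**Figure D2:**
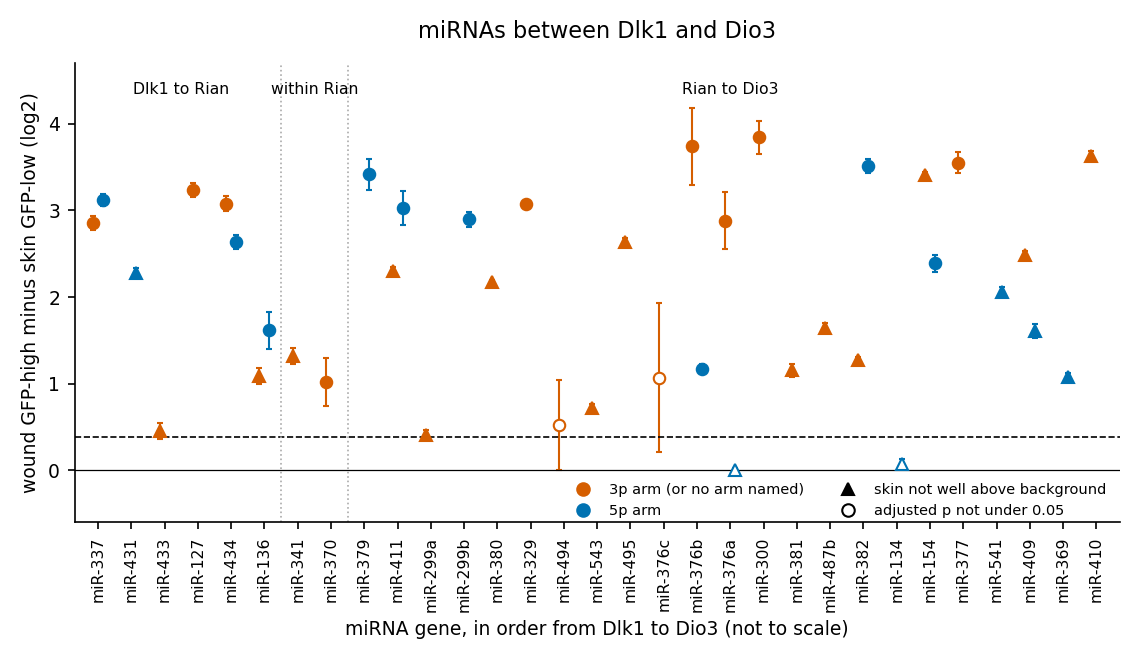
Log2 difference (wound GFP-high minus skin GFP-low, bars SE of the fit, 3 arrays per group) of the tested miRNAs between Dlk1 and Dio3, in gene order; triangles mark miRNAs not well above background in skin, open symbols those that did not pass, and the dashed line the median of all tested miRNAs. Raised miRNAs lie on both sides of Rian, up to 3.84 for miR-300-3p, and none is called lower, which the filter left hardly possible for the triangles.

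Outside the domain, miR-322-5p rose 10.8-fold (log2 3.44, SE 0.27) and its cluster neighbours miR-503-5p and miR-450a-5p were at least 10.72-fold and 2.65-fold higher, with no skin array well above background. These belong to an X-linked cluster whose members are known to restrain the cell cycle. All 4 tested members were higher (3 to 4 across the 5 scalings), the last being miR-542-3p (0.52). The list median was 2.24 (1.26 without wound preparation 3) and its adjusted p 0.064 in camera (0.596 with an estimated correlation, 0.0497 with the preset one without skin preparation 1); it passed under 3 other scalings. Among miRNAs induced in inflammation, 6 of 8 tested were higher and 0 lower (4 to 6 higher across scalings). The camera adjusted p was 0.093, and 0.614 with an estimated correlation. With the preset one the list passed with the percentile of all probes (0.015), median scaling (0.026) and no scaling (0.034), but not with quantile normalization. miR-21a-5p, an abundant miRNA linked to fibrosis, went from 2.01 ± 0.18 to 4.24 ± 0.05 (4.71-fold, adjusted p = 2.9e-05). miR-132-3p and miR-155-5p lay at the floor in skin and were 2.01 and 1.30 above it in the wound cells.

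On the lower side, the anti-fibrotic list held 12 lower, 2 higher and 3 not passing among 17 tested, with a median of -0.72 (-1.10 relative to the median of all tested miRNAs). That median ranged from -1.41 to 0.68 over the alternatives, positive only with normexp, where the median of all tested miRNAs was 1.03. Camera placed it below the other miRNAs (adjusted p = 2.5e-05), a call lost with an estimated correlation (adjusted p = 0.370), and 12 to 14 members were lower and 0 to 2 higher across the 5 scalings. The miR-29 family, which targets collagen and other matrix transcripts, was lower in all 3 of its 3p arms: the difference was -2.38 for miR-29b-3p, -2.29 for miR-29c-3p and -1.75 for miR-29a-3p (SE 0.28, 0.16 and 0.07). miR-101a-3p changed by -2.70 and miR-26b-5p and miR-26a-5p by -1.75 and -1.63. Over the alternatives other than left-out arrays and column numbers, miR-29a-3p and miR-26a-5p kept their calls. Smallest decreases there were -0.66 for miR-29b-3p, -0.90 for miR-29c-3p, -0.32 for miR-101a-3p and -1.16 for miR-26b-5p, and each of these lost its call in at least 1. The higher members were miR-19a-3p (1.71, lost under 1 scaling) and miR-19b-3p (0.78, lost under 2), which also belong to the miR-17-92 cluster, whose members promote proliferation.

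**Figure D3:**
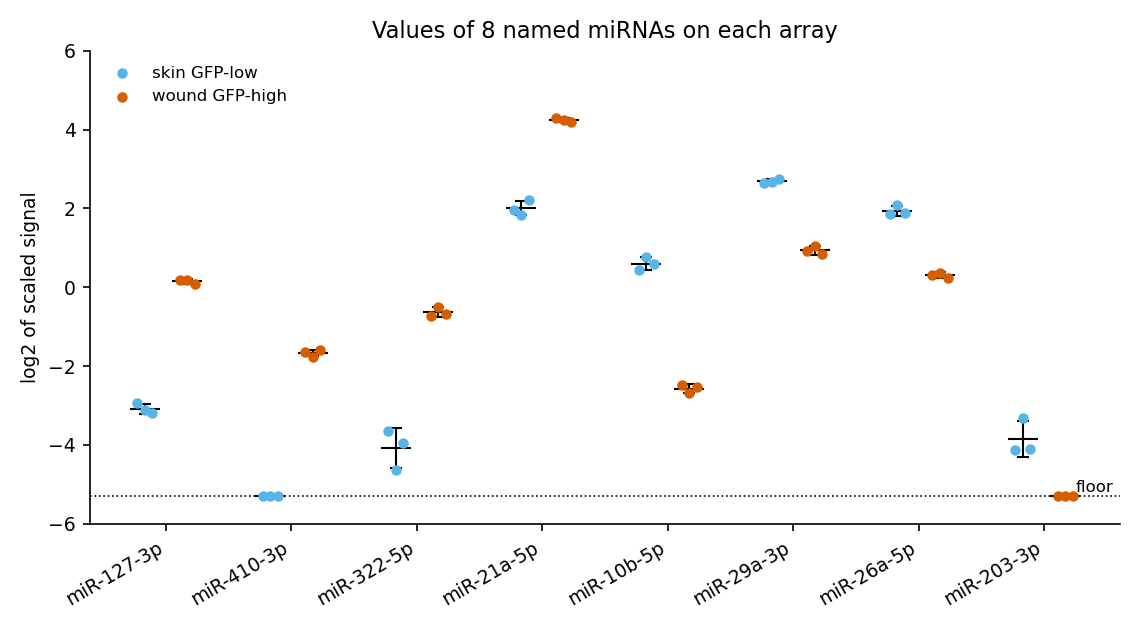
Log2 of the scaled signal of 8 named miRNAs on each of the 6 arrays (points), with the mean and SD of each group of 3 (bars); the dotted line is the floor at -5.30. The groups do not overlap for any of the 8; miR-127-3p goes from -3.09 to 0.15, and miR-410-3p in skin and miR-203-3p in wound lie at the floor.

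miR-10b-5p, encoded within a Hox gene cluster, had the largest decrease measured on both sides, from 0.60 ± 0.17 to -2.57 ± 0.11 (n = 3 each; a fold of 8.98, adjusted p = 8.7e-06). Further decreases measured on both sides were -2.34 for miR-181a-5p (0.32 with normexp, not passing), -2.13 for miR-218-5p, -1.997 for miR-23b-3p and -1.87 for miR-100-5p. Over the alternatives other than left-out arrays and column numbers, the last of these shrank to as little as -0.45, -1.40 and -0.79. Each lost its call in at least 1 (highest adjusted p in limma 0.496, 0.052 and 0.173, for miR-218-5p, miR-23b-3p and miR-100-5p in that order). miR-181c-5p was not well above background on any wound array and was at least 3.48-fold higher in skin, a direction that turned with normexp (0.86, not passing). With normexp the median of all tested miRNAs was 1.03, above the values of miR-181a-5p and miR-181c-5p. Of 9 tested let-7 family members, which are abundant in differentiated cells, 6 were lower, 1 (let-7e-5p, 0.41, which turned sign with scaling and is named after its value was seen) was higher and 2 did not pass. let-7c-5p and let-7b-5p changed by -0.88 and -0.76, and let-7g-5p by -0.47, a call lost under 1 of the 5 scalings. The family's camera adjusted p of 0.024 became 0.829 with an estimated correlation, 0.675 under quantile normalization and 0.059 without skin preparation 2. Lower members numbered 3 to 8 and higher members 0 to 2 across scalings.

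The lists linked to senescence and fibrosis held changes in both directions. Of 23 tested senescence-linked miRNAs 11 were higher and 6 lower (7 to 11 and 6 to 7 across scalings); miR-127-3p, miR-26b-5p and miR-29a-3p had the smallest p. That list's median was positive in the main setting (0.38) and negative under another scaling (-0.17), and camera placed it slightly below the others (adjusted p = 0.859). Of 15 pro-fibrotic miRNAs 7 were higher and 4 lower (7 to 9 and 3 to 5 across scalings; adjusted p = 0.850). The miR-34 family, targets of p53, had 3 of 3 tested higher in the main setting: miR-34b-5p and miR-34c-5p were at least 4.10-fold and 2.91-fold higher, while miR-34a-5p (0.53) turned sign under 3 scalings and lost its call without skin preparation 1 (family adjusted p = 0.290). In the miR-17-92 cluster and its paralogs 5 of 9 were higher, among them miR-19a-3p (1.71) and miR-18a-5p at 1.62 above the floor. miR-106b-5p was lower (-0.40, named after its value was seen). Across scalings 1 to 5 were higher and 1 to 3 lower, and the median turned from 0.47 to -0.32 (camera adjusted p = 0.608). Counts adjusted over the list alone equalled those over all tested miRNAs for each list, except 12 higher for the senescence list and 1 higher for miR-210-3p.

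Markers of other cell types moved in different directions. The keratinocyte miRNAs miR-203-3p and miR-205-5p were not well above background on any wound array and were at least 2.32-fold and 1.60-fold higher in skin. Both directions turned with normexp (0.95 and 0.97, not passing), where the median of all tested miRNAs was 1.03. The miR-205-5p call was lost when any of 4 arrays was left out (limma adjusted p up to 0.098). miR-31-5p was at least 2.72-fold higher in the wound cells (list adjusted p = 0.554). Of 19 keratinocyte names on the array only these 3 were tested. Of 12 blood cell names on the array 4 were tested. Among these miR-155-5p and miR-146a-5p (1.21, lost under 1 scaling) were higher, miR-181c-5p was lower and miR-342-3p (0.27) did not pass. miR-142-3p, miR-142-5p and miR-144-3p of that list, named after their values were seen, were not well above background on any array. That list's median of 0.74 and its fry direction differed in sign (camera adjusted p = 0.969, fry 0.095). Endothelial miR-126-3p differed by 0.50 (adjusted p = 0.109), turned sign with scaling (down to -0.38) and was called under 0 of the 5 scalings. Of the smooth muscle miRNAs miR-143-3p rose by 1.24, and miR-145a-5p, close to the floor, differed by 0.65, lost its call under 3 scalings and turned sign under quantile normalization (-0.04). None of the 8 skeletal and cardiac muscle names was tested, since none was well above background on all arrays of a group. The neural list held miR-132-3p, miR-212-3p (1.30, lost under 2 scalings) and miR-204-5p (-0.18, not passing), with an adjusted p of 0.608. In the adipocyte list 5 of 8 were higher and 2 lower (2 to 5 and 2 to 3 across scalings), with a median that turned sign with scaling (adjusted p = 0.969): miR-455-3p differed by 1.97, miR-455-5p was at least 2.02-fold higher and miR-378a-3p differed by 0.99, lost under 3 scalings. The hypoxia-induced miR-210-3p differed by 0.47 (adjusted p = 0.052), turned sign with scaling (down to -0.33) and was called under 0 of the 5 scalings. At other imprinted loci miR-335-5p was 2.47 above the floor and miR-296-5p differed by 0.70, the second lost under 3 scalings and without any 1 of 3 arrays. Of 8 tested miRNAs of the Sfmbt2 intron cluster 0 passed in limma under the main scaling (0 at an unadjusted p under 0.05) and up to 3 were lower under others. miR-669n differed by -0.50, miR-669a by -0.44 and miR-466c-5p by -0.40, each called under 2 of the 5 scalings (list adjusted p = 0.424, and 0.0476 without skin preparation 1).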

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

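The alternatives added after the data were seen are the authors' table matched by values, the run without names of old registry versions and membership by gene order. Leaving out 1 array at a time gave 127 to 136 changed miRNAs (83 to 92 higher, 38 to 49 lower, 62.9% to 70.3% higher), 33 to 35 higher Dlk1-Dio3 members, a list median of 2.25 to 2.34, and 3.18 to 3.32 for miR-127-3p. Lists called by camera then numbered 2 to 5: without skin preparation 1 the miR-322 and miR-503 list (adjusted p = 0.0497) and the Sfmbt2 list (0.0476) were added, and without skin preparation 2 the let-7 list was lost (0.059). Across the other alternatives, apart from the authors' table by column number, miR-127-3p stayed between 2.47 and 3.28 with adjusted p up to 0.0196, and the domain list passed in camera with adjusted p up to 2.3e-05. Its excess over the median of all tested miRNAs fell from 1.91 to 0.25 with normexp (list median 1.28), to 0.50 with a floor 4 times as high and to 0.04 with no filter, where most names lie at the floor. The excess grew to 3.07 with total signals, to 2.84 among miRNAs well above background on all arrays and to 2.73 with a lower floor. With an estimated correlation 0 lists passed in camera in the main setting (1 at an unadjusted p under 0.05) and 0 to 1 under the alternatives.

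The changed miRNAs numbered 23 with normexp (16 higher, 7 lower) and 78 with a floor 4 times as high (44 higher, 56.4% of calls). Higher calls numbered 52 with the percentile of all probes (76 lower, 40.6% higher), 54 without scaling (50.0%), 59 among miRNAs well above background on all arrays and 64 in the authors' table matched by values (49.6%); median scaling and quantile normalization gave 50.4% each. Higher domain members were 13 with normexp, 21 with the higher floor and 12 among miRNAs well above background on all arrays, where fewer are tested. With normexp, undetected miRNAs had median signals of 153 to 191 against a local background of 49.0 to 55.5, so background remained in dim signals. miR-181a-5p (0.32), miR-181c-5p (0.86), miR-203-3p (0.95) and miR-205-5p (0.97) turned sign there. The median of all tested miRNAs in that run was 1.03, above each of these values. Camera called 5 lists with the percentile of all probes, median scaling, no scaling, total signals, a lower floor or no filter, and 6 in the matched table; the miR-322 and miR-503 and the inflammation lists were added in each of these, and the cause was not tested. miR-34a-5p turned to -0.15 with the percentile of all probes, -0.0023 with quantile normalization and -0.0506 without scaling, and miR-145a-5p to -0.0447 with quantile normalization. 

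Taken by column number, the authors' table gave 1 changed miRNA (1 higher, 0 lower, 100% higher), 0 higher domain members, a domain median of -0.26 and -0.86 for miR-127-3p. By construction this grouping mixes arrays of both groups; other single miRNAs were not listed under it, and 47 of 52 called named miRNAs had the opposite sign with 0 called. Over all single results, 1241 outcomes of the other alternatives were graded the same, 86 lost and 33 gained a call. A further 32 counts or values moved, and 10 outcomes turned sign with a call in either setting. For left-out arrays these were 466, 9, 4, 1 and 0. The grade of same also covers counts that moved little and sign changes where neither setting passed. No paired analysis was possible because the sample numbers are not shared between the groups. Signal over background limits the dim miRNAs: 35 of the 144 calls rest on a bound (28 higher, 7 lower).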

Other observations

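Of the tests in this part, the 4 on the rise of the Dlk1-Dio3 miRNAs, the 2 on the deposited table's numbering, the one on both arms outside the domain and the one on unequal rises of retired names were chosen only after the result was seen. The others were fixed before their results. For the tests on shares of retired names, on the 2 segments and on both arms, however, the rules for reading the outcome differ from those written beforehand. Neighbouring miRNA genes outside the Dlk1-Dio3 domain had closer differences than random pairs. For 15 pairs of miRNAs with different numbers in their names, within 10000 bases of each other, each precursor's mean log2 difference was set against its neighbour's. Neighbours related in sequence were not removed by this rule, and cross-hybridisation between them was not tested. The mean absolute gap was 0.70, against a median of 1.47 for random pairings of the same values, and a share of 4e-04 of 10000 random pairings was as small (permutation test). Pairs chosen after their values were seen are miR-497 and miR-195a (-1.06 and -1.48), miR-23b and miR-27b (-1.997 and -0.90), miR-23a and miR-27a (-1.57 and -0.67), miR-212 and miR-132 (1.30 and 2.01) and miR-99b with let-7e (0.94 and 0.41). Of the 15 pairs 13 had the same sign; miR-93 and miR-106b (0.36 and -0.40) and miR-25 and miR-93 (-0.08 and 0.36) went apart, and miR-542 rose far less than miR-503 (0.52 and 3.25). Shared transcription of a cluster is a candidate explanation; a common scaling factor cancels within a pair, but chains and paralogous clusters make the pairs less than independent.

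Both arms were tested for 21 precursors, of which 14 had arms of the same sign, 6 had an arm at the floor and miR-1839 had opposite signs (0.10 and -0.38). The mean absolute gap was 1.02 against a random median of 1.64, and a share of 0.0026 of random pairings was as small. Of the 21 precursors 9 lie in the Dlk1-Dio3 domain, whose rise alone brings its arms together. Among the other 12 (6 with the same sign, 5 with an arm at the floor) the gap was 0.82 against 0.96, with a share of 0.148, so joint change of the arms stays open. The domain's 2 segments on either side of Rian had means per precursor of 2.19 ± 1.09 (SD, 6 precursors) and 2.12 ± 1.09 (21 precursors). Their difference of -0.07 (SE 0.50; permutation p = 0.888) leaves differences of 1 SE or more to either side open, so the test decides nothing about equal changes.

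Many of the raised Dlk1-Dio3 miRNAs are dim, but the list's median of 2.29 lay above the central 95% of 10000 random lists matched on mean level, whose upper limit was 0.52. Cross-hybridisation among the related distal members leaves out the 9 tested members between Dlk1 and Rian, whose median was 2.64 with 9 higher. Among these miR-433-3p was called under only 1 of the 5 scalings. A scaling by 1 factor per array moves all miRNAs alike and tests nothing here, while under quantile normalization the list's median stayed 1.86 above that of all tested miRNAs. With normexp that excess was only 0.25. That run also took the median signal and added an offset, so the smaller excess cannot be put down to background handling alone. The list's median of 1.28 in that run still lay above the upper limit of 1.05 of random lists matched on level. What stays open is the biology that the design confounds: tissue, injury and GFP level, and a change in which cells pass the gate, were not separated, and a shared regulation of the domain in wound myofibroblasts may be put forward only as a hypothesis.

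Names that carry an old registry version, many of them since withdrawn as fragments of other RNAs, took 56.7% ± 4.53 (SD, n = 3) of the summed signal on the skin arrays and 71.8% ± 3.01 on the wound arrays (exact permutation p = 0.1, the smallest possible). Most of the rise came from miR-2142 (mean share 31.9% to 41.6%) and miR-1937b (14.6% to 19.5%), while miR-2141 (3.15% to 3.25%) and miR-2138 (1.30% to 1.23%) hardly moved. A share within an array takes no scaling factor, so the scaling cannot make this difference; without scaling the median of the 20 tested retired names was -0.26, inside the central 95% of lists matched on mean level (-1.15 to -0.19, median -0.63), so their median log2 difference shows no rise beyond that of other names. Only 45% lay above the median of all tested miRNAs, a reference not matched on level, and rises among the 19 names well above background on all arrays were unequal (F = 2.64 for name by group), but more so under another split of the arrays (3.22), so a common factor stays open. In unscaled signal the wound arrays' sum was 114% of the skin arrays' for these names and 58.5% for current names, and a lower amount of current miRNAs per labelled RNA in the wound preparations may underlie the share; that was not tested, and the biological difference between the groups stays untested.

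In the deposited log2 table, columns 1, 2, 3, 4, 5 and 6 hold the arrays titled 3, 4, 6, 1, 2 and 5. Over the 656 of 691 rows with names found in the scanner files, all 6 columns equal exactly 1 array each apart from a constant, which fits numbers given in another order, with the wound arrays first. The reading that the titles are wrong and the column numbers right is opposed by the counts, since grouping the arrays by the column numbers called 0 miRNAs (0 at an unadjusted p under 0.05 in limma) against 144 by the titles. An exchange of both groups as a whole would turn every direction without changing that count, and no test here excludes it.

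With 3 against 3 arrays there are only 10 splits, too few for a share under 0.05. The real split called 144 miRNAs, as 1 of the 10, and the highest of the others called 0 (and at most 8 at an unadjusted p under 0.05 in limma). For lists called by camera with the preset correlation the real split gave 3 and the highest other split 3, and 4 of the 10 splits gave as many. Every other split called at least 1 list while calling 0 miRNAs. Each of these splits still held more skin arrays on 1 side and more wound arrays on the other. Part of the group difference thus stayed in the contrast, and the rest widened the spread within its sides. The other splits are therefore no reference without a group difference, and neither count decides whether calls arise without one.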
